A study of Mus musculus with 12 samples.

How the data were processed

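Messenger RNA was measured in colon samples of male mice on Illumina bead arrays, on which each gene is read by 1 or more probes attached to beads. Per the labels, total RNA was extracted with Trizol, purified on RNeasy columns and copied into biotinylated cRNA with the Ambion MessageAmp kit. The 12 arrays fall into 4 groups of 3 by their treatment labels: control, DSS, DAPP before DSS and DAPP during DSS. DSS is dextran sulfate sodium, a chemical that injures the colon lining and is widely used to induce colitis in mice. DAPP is the abbreviation given in the labels, and the series title concerns polyphenols of apple peel. The deposited column names carry the number 200 for DAPP before DSS and 400 for DAPP during DSS, with no unit, so that timing and this number differ together between the DAPP groups. The labels call the samples of a group biological replicates. They give the sex and an age of 7 to 8 weeks, and further detail on the animals, such as a vehicle for the control mice, is not given in the sources used here. The p-values measure the spread between these samples.

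The deposited table of unnormalised data holds, for each array, the signal intensity of 45281 probes on a linear scale and, per the file headers, a detection p-value for each probe. Per the submitters' processing notes the arrays were summarised in GenomeStudio, and the version and the handling of the background are not given in the sources used here. The lowest intensities of the deposited columns lie well above 0, so it was inferred, but is not stated, that no background had been subtracted. A further 1949 lines of that table are blank and were left out. The authors' processed values of the same arrays are intensities on a linear scale. Their columns have medians of 146.5 to 146.6 and means of 567, and their ranks are those of the unnormalised columns (Spearman correlation 1 for each array). These values therefore look quantile-normalised, neither centred nor log-transformed, which was inferred from the values. They were used as an alternative. All signal columns matched a sample by name, and 0 columns were left unused. No sequence alignment or genome build enters array data of this kind, and no coordinates are given.

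Intensities were corrected for background with limma's neqc function, which estimates the background of each array from the signals and detection p-values, adds an offset of 16, normalises the arrays to common quantiles and takes log2 (R 4.3.3, limma 3.58.1). A probe was kept when its detection p was under 0.05 on at least 3 of the 12 arrays, which left 22359 probes. Probes were named through the platform's annotation table, in which 34885 probes have 1 gene symbol, 18 have several and 10378 have no gene listed. Symbols were updated through the Entrez identifier to a gene table of the mouse assembly GRCm38.p6, where 34807 of the 34885 matched. Of the kept probes, 18852 had 1 symbol. Each gene was represented by its kept probe with the highest mean, which gave 11933 genes, 4638 of them with more than 1 kept probe. Of the genes changed between DSS and control, 310 had another kept probe, and for 23 of them a further probe had the opposite sign.

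A linear model with the 4 groups was fitted to all 12 arrays (lmFit and eBayes in limma, 8 residual and 3.95 prior degrees of freedom), so that all comparisons share 1 estimate of the spread. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 11933 genes. The 6 comparisons are DSS against control, each DAPP group against DSS, the DAPP groups against each other, and each DAPP group against control. Where a gene was not detected on any array of the dimmer group, its change is a bound, given as at least N-fold: the mean of the brighter group was set against the mean of, per array, the higher of the lowest signal among detected probes and the gene's own signal. That lowest detected signal was 5.18 to 5.70 on the log2 scale.

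The tissue-specific and pathway gene lists, the comparisons, the tests, the rule for named genes and all alternatives other than those said below to be added were fixed before the data were examined. The 37 lists hold 770 members, of which 695 matched a gene on the array. In all, 36 lists had at least 5 tested members and were tested. The adipocyte list, with 4 tested members, was not tested as a list. Each list was set against all other genes with limma's camera test at its preset correlation of 0.01 between genes, with adjustment over the 36 lists, and again with a correlation estimated from the residuals. The fry test of limma, which asks whether the members of a list move on balance 1 way, was run as a further alternative. For each list the members past 0.05 were counted over all genes tested and after adjustment over the list alone. The median of a list with undetected members was computed again with those members at their bounds.

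For the comparisons of DSS with control and of each DAPP group with DSS, the text names the 12 largest rises and the 12 largest falls among called genes whose 3 arrays per group do not overlap, leaving out predicted genes. Where fewer than 5 genes passed, it draws on the 6 genes with the smallest p per direction, as genes not past the threshold. Other comparisons take 6 genes per direction. Up to 3 members per list with the smallest p, and a fixed set of 21 genes of inflammation, barrier, oxidative stress and mitochondria, complete the rule. Of these 21, 20 were tested, and Mpo did not pass the detection filter.

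The position of each DAPP group between DSS and control was measured as the slope of its difference from DSS on the DSS-minus-control difference, over genes called between DSS and control. The genes and that difference came from the arrays other than 1 held-out DSS array, which alone served as the DSS level in the other difference. On this scale -1 is the control level and 0 the DSS level. Chance correlation between comparisons that share arrays was obtained from 100 simulations with no effect. Lists were also set against 10000 random lists of the same size matched on mean expression.

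The steps were tested on simulated data with 200 of 11933 genes changed. For DSS against control the model recovered 28% of the genes changed by a log2 of 1 and 91% of those changed by a log2 of 2. For DAPP before DSS against DSS these shares were 21% and 93%, and for DAPP during DSS against DSS they were 24% and 92%. False calls made up 1.71% to 6.56% of the calls over the 6 comparisons. The simulated genes varied independently of each other, with the same spread on every array and no outlying array. The real arrays differ in this, so these shares may not hold for them. The slope measure returned -0.94 and -0.95 for the DAPP groups where the simulated return was complete.

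Alternatives were no background correction (signals under 1 set to 1), an offset of 50, scaling to equal medians in place of quantiles, the authors' processed values, no detection filter, detection p under 0.01 on all 12 arrays, all kept probes in place of 1 per gene, the replicate number as a block, only the 2 groups compared, eBayes with trend and robust settings, array weights, a fold of at least 1.5, each array left out in turn, the other list tests, and all tested genes for the slope. Added after seeing the data were the mean of the pancreas list as a covariate and the slope with arrays left out. The mean raw signal was 433 to 507 on the control and DSS arrays and 601 to 728 on the DAPP arrays. The number of probes detected was 17650 to 21444 per array (39.0% to 47.4%). The number of arrays, 3 per group, limits the precision of every value. The smallest p of an exact permutation test of 3 arrays against 3 is 0.1, so single values were not tested that way.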

Results

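Transcript levels were measured in the colon of 12 male mice, 3 in each of 4 groups: control, DSS (dextran sulfate sodium, a chemical that induces colitis), DAPP before DSS, and DAPP during DSS. DAPP is named only by this abbreviation in the labels, under a series title on apple peel polyphenols in experimental inflammatory bowel disease. The design asks how DSS changes the colon, whether DAPP given before or during DSS leaves the colon closer to control, and whether the DAPP groups differ from each other. Levels are normalised log2 intensities of 11933 genes, errors of differences are standard errors from limma's model over 3 arrays per group, and group means are given with the SD of 3 arrays. Between 17650 and 21444 probes were detected per array. The mean raw signal was 433 to 507 on the control and DSS arrays and 601 to 728 on the DAPP arrays, with no overlap. Replicate 1 of DAPP before DSS correlated at 0.828 to 0.914 with the other 11 arrays over genes, where all other pairs of arrays lay between 0.916 and 0.984. The first principal component held 42.6% of the variance and the second 21.9%.

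The colon of DSS-treated mice carried far more transcripts of neutrophils, cytokines, acute phase proteins and matrix-degrading enzymes than the control colon, and fewer transcripts of smooth muscle and of drug-metabolising enzymes. The list calls for smooth muscle and xenobiotic metabolism were lost with an estimated correlation (adjusted p = 0.15 and adjusted p = 0.268 with an estimated correlation). S100a9 (Entrez 20202) and S100a8 (Entrez 20201), the calprotectin subunits carried by neutrophils, rose 138-fold and 116-fold. The S100a9 level was 12.95 ± 0.90 in DSS and 5.85 ± 0.08 in control (SD, n = 3 each). Reg3b (Entrez 18489), an antibacterial lectin of the gut lining, rose from 6.67 ± 1.09 to 14.22 ± 0.97, and Lcn2 (Entrez 16819), which withholds iron from bacteria, rose 78.6-fold. In the opposite direction Slc37a2, a sugar-phosphate transporter, was 19.5-fold lower, and the pentraxin Mptx1 fell from 14.46 ± 0.31 to 10.40 ± 0.81.

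In all, 801 of 11933 genes differed between DSS and control at an adjusted p under 0.05 in limma, 466 higher and 335 lower. Of these, 697 changed over 2-fold and 230 over 4-fold, and 110 of the higher ones were not detected on any control array. The 3 arrays per group did not overlap for 30.5% of all genes, where chance gives 10%. The count was 493, 484 and 467 without control replicates 1, 2 and 3, 429 without DSS replicate 1, and 1523 without replicate 1 of DAPP before DSS, which adds to the shared estimate of spread. With the pancreas list mean as a covariate it was 606, of which 560 were among the 801.

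**Figure D1:**
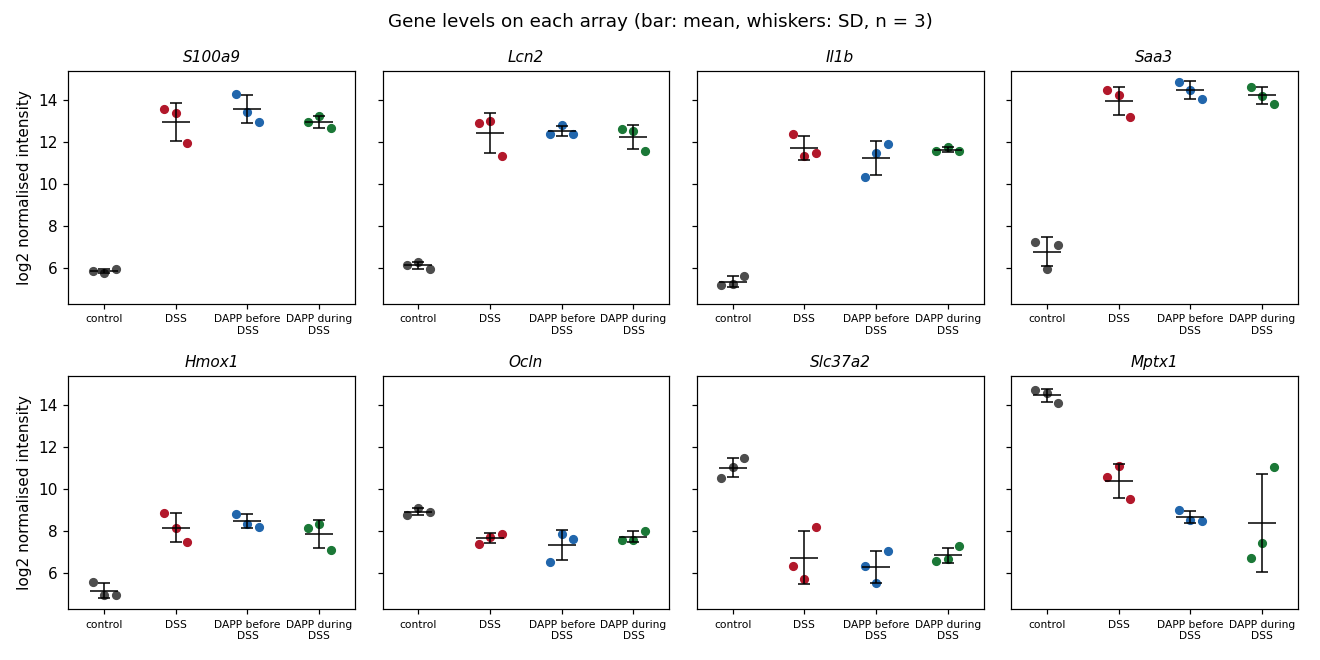
Normalised log2 intensity (y axis) of 8 genes on each of the 12 arrays by group (x axis), with the group mean and SD. S100a9, Lcn2, Il1b, Saa3 and Hmox1 lie higher on all DSS and DAPP arrays than on any control array, and Ocln, Slc37a2 and Mptx1 lie lower.

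Neutrophil genes rose together. Of 19 members 17 rose over all genes tested (18 adjusted over the list alone), and 2 did not pass, with a list median of 3.91 on the log2 scale, or 3.28 with undetected members at their bounds (camera adjusted p = 2.47e-31). Il1b rose by 6.37 ± 0.38 (limma adjusted p = 1.7e-06), from 5.34 ± 0.25 in control to 11.71 ± 0.56 in DSS. Among inflammatory cytokines and acute phase proteins 19 of 26 rose (22 adjusted over the list alone), with a median of 3.33 and a median at bounds of 2.54 (adjusted p = 4.87e-31). The acute phase genes Saa3 and Hp rose by 7.19 ± 0.41 and 5.57 ± 0.31, and the neutrophil-attracting chemokine Cxcl1 by 6.02 ± 0.54. Tnf, a central inflammatory cytokine, rose by 1.97 ± 0.38 (limma adjusted p = 0.0076). Il6 was not detected in control and was at least 6.02-fold higher in DSS (limma adjusted p = 0.0047). Macrophage and monocyte genes rose in 11 of 16 cases (14 adjusted over the list alone), with a median of 1.70 (adjusted p = 4.35e-15). Among them were the complement gene C1qb, by 1.93 ± 0.24, the lipopolysaccharide co-receptor Cd14, by 1.89 ± 0.23, and Chil3, a chitinase-like protein that was at least 48.3-fold higher. In the matrix and remodelling list 14 of 23 genes rose (18 adjusted over the list alone), with a median of 1.41 (adjusted p = 6.26e-20). The metalloproteinases Mmp10 and Mmp3 rose by 6.63 ± 0.32 and 5.77 ± 0.42, and their inhibitor Timp1 by 4.49 ± 0.30. These 4 lists also passed with an estimated correlation, at adjusted p = 0.0368 for neutrophils, 0.0313 for cytokines, 0.0368 for matrix and 0.0498 for macrophages. Over the alternatives other than an estimated correlation and fry the matrix list, for example, had an adjusted p of 1.52e-22 to 3.3e-13. With no background correction the medians were 2.04 for neutrophils and 1.78 for cytokines, on the authors' values 2.02 and 1.76, and with detection p under 0.01 on all 12 arrays 1.74 for cytokines. Further genes among the 12 largest rises were Clca4b, by 7.04 ± 0.42, Retnlg, by 6.53 ± 0.46, and Wfdc12, at least 47.5-fold higher. Il1b, Tnf, Retnlg, Hmox1, Cd3e, Icos and Cpa1 were detected on 1 of 3 control arrays and Reg3b on 2 of 3, so their differences carry the background level of the other control arrays.

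Interferon-response genes and T and NK cell genes also rose as lists at the preset correlation of camera. For interferon 7 of 23 members rose (11 adjusted over the list alone), with a median of 1.10 and an adjusted p = 1.67e-07, and adjusted p = 0.353 with an estimated correlation. The chemokine Cxcl9 rose by 5.25 ± 0.80, the peptide transporter Tap1 by 2.28 ± 0.38 and Ifit2 by 1.81 ± 0.36. In the T and NK cell list 5 of 11 rose (7 adjusted over the list alone), among them Cd3e, a chain of the T cell receptor complex, by 2.04 ± 0.37, and Icos by 1.93 ± 0.28. The list median was 1.59 (adjusted p = 3.15e-05, and adjusted p = 0.268 with an estimated correlation), 0.82 with no background correction, 0.81 on the authors' values and 0.69 with no detection filter. The interferon median was 0.69 and 1.68 without DSS replicates 1 and 3, and 1.71 with the pancreas list mean as a covariate. Of 20 epithelial antimicrobial genes 6 rose and 1 fell (11 and 3 adjusted over the list alone), with a median of 1.81, a median at bounds of 1.49 and an adjusted p = 7.38e-06 (adjusted p = 0.117 with an estimated correlation). That median was 1.01 with no background correction and 1.04 without control replicate 3. Besides Reg3b, Ido1 rose by 5.43 ± 0.53, and the protease inhibitor Slpi by 3.34 ± 0.38. MHC class II genes had a median of 0.98, with 1 of 11 past the threshold (adjusted p = 0.00113, and adjusted p = 0.355 with an estimated correlation), and a median of 0.57 without DSS replicate 1. The mast cell and eosinophil list had a median of 0.63 with 2 of 6 members higher (3 adjusted over the list alone) and an adjusted p = 0.0286. That call was lost at adjusted p = 0.15 with an estimated correlation, at 0.0601 without DSS replicate 2, with equal medians (0.0563) and with array weights (0.0505). It was also lost with no background correction (median 0.21, adjusted p 0.0596), an offset of 50 (0.38 and 0.061) and the authors' values (0.21 and 0.0594), and with no detection filter the median turned to -0.05 (0.316). B and plasma cell genes did not pass as a list (adjusted p = 0.867).

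Smooth muscle genes fell. Of 13 members 8 were lower (10 adjusted over the list alone), with a median of -1.19 and an adjusted p = 1.55e-08 (adjusted p = 0.15 with an estimated correlation). The actin-binding protein Tagln stood at -1.59 ± 0.22 and the actin filament nucleator Lmod1 at -1.49 ± 0.25, both past the threshold. Genes of the aryl hydrocarbon receptor and xenobiotic metabolism fell in 4 of 17 cases (6 adjusted over the list alone), with a median of -0.89 and an adjusted p = 0.000173 (adjusted p = 0.268 with an estimated correlation). That median was -0.53 with no background correction and on the authors' values, -0.57 with an offset of 50, -0.35 with no detection filter and -0.47 without DSS replicate 1. The epoxide hydrolase Ephx1 fell by 1.64 (SE 0.21). Outside that list the cytochrome P450 genes Cyp2d12 and Cyp2f2 were among the 12 largest falls, at -3.33 ± 0.46 and -3.30 ± 0.57. Others were Mettl7a2 at -4.35 ± 0.28 (limma adjusted p = 3.4e-06), Odf3b at -3.31 ± 0.33, the transglutaminase Tgm3 at -3.17 ± 0.59, the neuropeptide gene Nmu at -2.97 ± 0.44 and Bex4 at -2.93 ± 0.35. Cyp2f2 and Mettl7a2 were detected on 1 of 3 DSS arrays. The Mptx1 fall had a limma adjusted p of 0.013, and 0.0533 without control replicate 1.

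Lists of epithelial function and metabolism showed small shifts. The mitochondrial biogenesis and tricarboxylic acid cycle list had a median of -0.35 with 1 of 22 members lower (3 adjusted over the list alone), at adjusted p = 0.00113 and adjusted p = 0.0971 with an estimated correlation, and a median of -0.23 with equal medians. Oxidative phosphorylation did not pass, with a median of -0.13 over 40 genes (adjusted p = 0.223). Absorptive colonocyte genes had a median of -0.36 with 1 of 27 higher and 1 lower (1 and 5 adjusted over the list alone), at adjusted p = 0.0222 and adjusted p = 0.575 with an estimated correlation. Without control replicate 1 and without DSS replicate 1 that list stood at adjusted p values of 0.0527 and 0.177, with medians of -0.35 and -0.22, and with detection p under 0.01 on all 12 arrays at 0.104. Its median was -0.18 with equal medians. Tight and adherens junction genes had a median of -0.24 with 2 of 19 lower (3 adjusted over the list alone), at adjusted p = 0.0438 and adjusted p = 0.505 with an estimated correlation, and at 0.114 without control replicate 3, 0.15 without DSS replicate 1 (median -0.16) and 0.0517 without replicate 3 of DAPP before DSS. With equal medians that median was -0.08 and the call was lost (0.084). The tight junction protein Ocln fell by 1.27 (SE 0.31), with a limma adjusted p of 0.029 that became 0.0682, 0.112 and 0.0893 without control replicates 1, 2 and 3, and 0.125 and 0.065 without DSS replicates 1 and 2. Clock genes had a median of -0.45 with 1 of 13 higher and 1 lower, the output factor Dbp at -2.43 ± 0.35. That list had an adjusted p = 0.0222, and adjusted p = 0.383 with an estimated correlation, and lost its call without control replicate 3 (0.0806), DSS replicate 1 (0.0585) and DSS replicate 3 (0.0541), and with detection p under 0.01 on all 12 arrays (0.119). Its median was -0.25 with no background correction and on the authors' values. Goblet cell genes had a median of -0.26 (adjusted p = 0.317), and their main mucin Muc2 stood at -0.42 ± 0.48. Muc2 was at 13.51 on DSS replicate 1 and at 14.82 and 14.75 on DSS replicates 2 and 3, against 14.77 to 14.80 in control, near the highest level of any probe (15.09). Without DSS replicate 1 the Muc2 difference was 0.0090.

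In the list of NRF2 antioxidant genes, which belong to the oxidative stress response, 3 of 21 rose (3 higher and 1 lower adjusted over the list alone), with a median of -0.01, a mean of 0.21 and no call (adjusted p = 0.306). Hmox1, which degrades heme, rose by 2.99 ± 0.39 (limma adjusted p = 0.00071), while Nqo1 stood at -0.46 ± 0.46 and Nfe2l2, the gene of NRF2 itself, at -0.02 ± 0.52. Other antioxidant enzymes had a median of 0.00 with 3 of 17 higher (4 adjusted over the list alone, list adjusted p = 0.124), among them the metallothionein Mt1, by 1.31 ± 0.20 to a level of 14.93, near the highest of any probe (15.09), and Gpx3, by 1.97 ± 0.35. Sod2, Gpx1 and Cat did not pass, at 0.44 ± 0.24, 0.32 ± 0.36 and -0.57 ± 0.32. Ppargc1a, a regulator of mitochondrial biogenesis, stood at -1.77 ± 0.66 (limma adjusted p = 0.16), and its downstream factor Tfam at -0.27 ± 0.24. The inducible nitric oxide synthase Nos2 was not detected in control and was at least 2.54-fold higher, without passing (limma adjusted p = 0.059). Cldn2 and Tjp1 did not pass either, at 0.11 ± 0.57 and -0.48 ± 0.22.

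Smaller lists with a call were the unfolded protein response, fibroblasts and endothelium. The first had a median of 0.35 with 2 of 21 higher, Chac1 by 1.99 ± 0.33 (list adjusted p = 0.0134, and adjusted p = 0.117 with an estimated correlation), and lost its call with detection p under 0.01 on all 12 arrays (0.0789). Fibroblast genes had a median of 0.45 with 3 of 13 higher (4 higher and 1 lower adjusted over the list alone), among them the BMP antagonist Grem1 by 2.46 ± 0.38 (list adjusted p = 0.0154, and adjusted p = 0.327 with an estimated correlation), and a list median of 0.23 without DSS replicate 1. Endothelial genes had a median of 0.41, or 0.32 at bounds, with 0 of 13 past the threshold. Their adjusted p = 0.0438 became adjusted p = 0.423 with an estimated correlation, and was 0.0686 and 0.0573 without control replicates 1 and 2 and 0.15 and 0.0684 without DSS replicates 1 and 2, and 0.0784 with equal medians. The endothelial median was 0.62 without DSS replicate 3 and 0.66 with the pancreas list mean as a covariate. Cell cycle, cholesterol synthesis and ribosomal protein lists did not pass (adjusted p = 0.517, 0.841 and 0.903), nor did fatty acid oxidation (0.139), immediate early genes (0.212), stem cell and Wnt genes (0.265), enteric neurons and glia (0.24), enteroendocrine cells (0.263), red blood cells (0.0678), skeletal muscle (0.172), small intestine and Paneth cells (0.348) and squamous epithelium (0.494).

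Genes of the exocrine pancreas were high on some arrays of the DSS and DAPP groups. The mean of 14 pancreatic enzyme genes was 7.70, 6.07 and 5.98 on the control arrays, 6.29, 12.8 and 13.5 on the DSS arrays, 13.4, 11.8 and 12.6 in DAPP before DSS, and 8.53, 5.81 and 13.8 in DAPP during DSS. As a list they had a median of 4.88 for DSS against control (adjusted p = 8.47e-05, and adjusted p = 0.423 with an estimated correlation), with 0 of 14 genes past the threshold and 13 of 14 positive. That median was 7.59 without DSS replicate 1. The amylase gene Amy2a5 stood at 3.80 ± 1.45 and the carboxypeptidase gene Cpa1 at 5.13 ± 2.15. Reg1 and Reg2 moved with these enzymes from array to array, Reg2 being at 6.28 on DSS replicate 1 and at 14.24 and 13.69 on DSS replicates 2 and 3. Reg3b was at 13.12, 14.98 and 14.54 on the same arrays, the second of these near the highest level of any probe (15.09), where a difference can be understated.

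**Figure D2:**
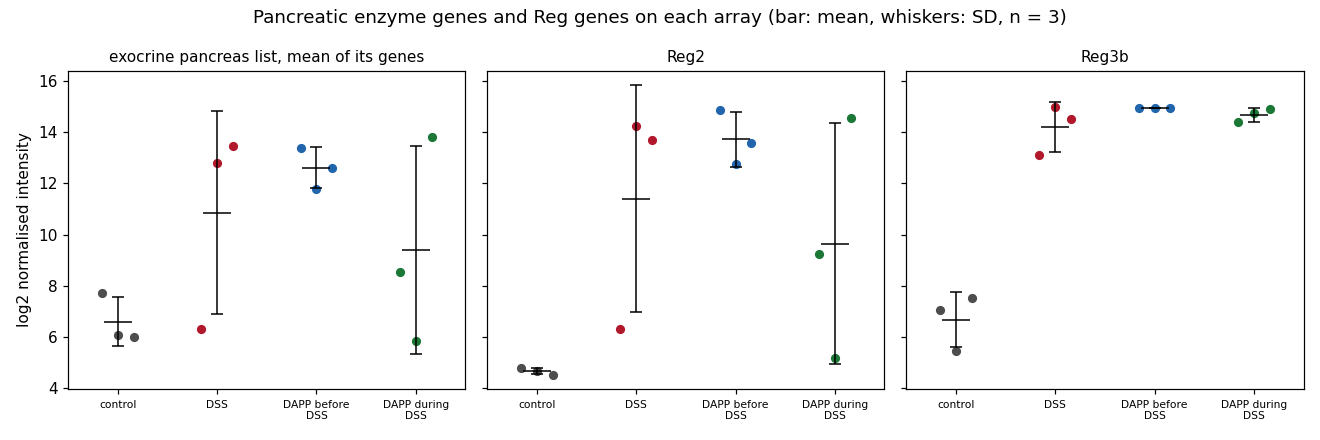
Log2 intensity (y axis) of the pancreas list mean and of Reg2 and Reg3b on each array (x axis, grouped by treatment). The list mean and Reg2 are high on the same arrays, among them DSS replicate 3 (13.5) but not DSS replicate 1 (6.29), whereas Reg3b lies above 13 on every DSS and DAPP array.

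In mice given DAPP before DSS no single gene passed the test against DSS. The neutrophil genes S100a8 and S100a9 stood at 0.16 ± 0.37 and 0.60 ± 0.42 relative to DSS, Lcn2 at 0.11 ± 0.42, and the cytokines Il1b, Il6 and Tnf at -0.47 ± 0.38, -0.01 ± 0.61 and -0.12 ± 0.38. The 95% interval was -1.29 to 0.35 for Il1b and -0.80 to 1.01 for Lcn2, against DSS-minus-control rises of 6.37 and 6.30. Small shifts of whole lists were seen at the preset correlation of camera: matrix, immediate early, endothelial and pancreatic genes lay higher than in DSS, and cell cycle, colonocyte, cholesterol synthesis and oxidative phosphorylation genes lay lower. None of these 8 calls held, each with adjusted p = 0.86 with an estimated correlation.

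For this comparison limma called 0 of 11933 genes (smallest adjusted p 0.85). At an unadjusted p under 0.05 there were 535 genes, 597 being the number no effect would give. This does not show that there was no effect, since replicate 1 of DAPP before DSS adds to the shared estimate of spread. The count was also 0 with array weights, with eBayes trend and robust settings, with the replicate block and on the authors' values. The 3 arrays per group did not overlap for 6.48% of genes, where chance gives 10%. The smallest p among higher genes included Hoxa11, a homeobox factor, at least 2.06-fold, the interleukin 4 receptor gene Il4ra at 1.12 ± 0.26, Gdf10 at 0.96 ± 0.23, Tspyl2, at least 1.24-fold, and Npy4r at 0.89 ± 0.21. Among lower genes were Sorbs2 at -1.40 ± 0.36, the magnesium channel Trpm6 at -1.36 ± 0.29, Zfp994 at -1.23 ± 0.30, Arid4b at -1.10 ± 0.29 and the kinase Akt1, at least 1.16-fold lower. Il4ra was detected on 1 of 3 DSS arrays, and Sorbs2, Zfp994 and Arid4b on 2 of 3 arrays of DAPP before DSS. All of these had an adjusted p of 0.85.

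The list shifts were small, held no member past the threshold over all genes or adjusted over the list alone, and each had adjusted p = 0.86 with an estimated correlation. Matrix and remodelling genes had a median of 0.36 with 17 of 23 positive (adjusted p = 0.00905), led by the collagens Col5a2 at 0.78 ± 0.33 and Col3a1 at 0.71 ± 0.23. That call was lost without DSS replicates 2 and 3 (0.0743 and 0.112) and without replicates 2 and 3 of DAPP before DSS (0.34 and 0.103), the median being 0.20 without DSS replicate 3 and 0.24 without DAPP before DSS replicate 2, and its adjusted p ranged from 1.87e-08 to 0.34 over the alternatives other than an estimated correlation and fry. Its median was 0.58 with equal medians. Immediate early genes had a median of 0.41 with 15 of 18 positive (adjusted p = 0.00976), Egr1 at 0.64 ± 0.31 and Zfp36 at 0.61 ± 0.22, and lost the call without DSS replicates 2 and 3 (0.0642 and 0.0772) and DAPP before DSS replicate 2 (0.129), and with array weights (0.0588). Their median was 0.64, 0.27 and 0.18 without DSS replicates 1, 2 and 3, 0.15 and 0.48 without DAPP before DSS replicates 1 and 2, 0.18 with array weights, and 0.27 with no background correction and on the authors' values. Endothelial genes had a median of 0.25 with 11 of 13 positive (adjusted p = 0.0494), Pecam1 at 0.96 ± 0.34. Their adjusted p rose over 0.05 without each control array (0.0535 to 0.0564), without DSS replicates 2 and 3 (0.15 and 0.24), without DAPP before DSS replicates 2 and 3 (0.34 and 0.103), without DAPP during DSS replicate 2 (0.0504) with equal medians (0.0774) and with no detection filter (0.0767). Their median was 0.14 without DSS replicate 3 and 0.38 without DAPP before DSS replicate 3. Cell cycle genes had a median of -0.43 with 1 of 23 positive (adjusted p = 0.00905), among them the thymidylate synthase gene Tyms at -1.02 ± 0.43 and the topoisomerase gene Top2a at -0.82 ± 0.47. Without DAPP before DSS replicate 2 that median was -0.06 (adjusted p = 0.871), and the call was also lost without DSS replicates 1 and 3 (0.177 and 0.0769) and with array weights (median -0.27, adjusted p 0.0588). It was -0.24 and -0.78 without DSS replicates 1 and 2, and -0.94 without DAPP before DSS replicate 3.

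Replicate 1 of DAPP before DSS stood apart from the other arrays, and several lists moved with it. The median deviation from the other arrays of its group was -1.28 for colonocyte genes, and goblet cell genes deviated by -0.94, cholesterol synthesis genes by -0.79, matrix genes by -0.64, and B and plasma cell genes by 2.05. Colonocyte genes had a median of -0.33 relative to DSS (adjusted p = 0.0228), the transporter Slc5a8 at -0.88 ± 0.36 and the carbonic anhydrase Car1 at -0.49 ± 0.23. The median turned to 0.12 without that array (adjusted p = 0.382), and the call was lost without DSS replicates 2 and 3 (0.361 and 0.208). With array weights the median turned to 0.03 and the call was lost, and with equal medians it was -0.18. It was -0.58 and -0.16 without DSS replicates 1 and 3, and -0.69 without DAPP before DSS replicate 2. Cholesterol synthesis genes had a median of -0.40 (adjusted p = 0.0459), Mvd at -0.72 ± 0.32 and Cyp51 at -0.67 ± 0.35. That median was -0.09 (0.483) without the same array, and the call was lost without DSS replicate 3 (median -0.23, adjusted p 0.541), DAPP before DSS replicate 3 (0.103) and control replicates 2 and 3 (0.0504 and 0.0505), and with array weights (median -0.23, adjusted p 0.121). Ppargc1a was at 5.18 on that array and at 8.69 and 7.41 on the other arrays of the group, giving -1.39 ± 0.66 relative to DSS. Muc2 was at 12.87 there and at 14.89 and 14.85 on the others, giving -0.16 ± 0.48. Its sign turned without that array (0.50), without DSS replicates 2 and 3 (0.07 and 0.04), with equal medians (0.32, the median of all genes being 0.13) and with array weights (0.44), and without DSS replicate 1 it was -0.59.

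Oxidative phosphorylation genes had a median of -0.14 with 13 of 40 positive (adjusted p = 0.0494). The call was lost without any 1 array other than replicate 1 of DAPP before DSS (adjusted p 0.0504 to 0.175), and with equal medians, where the median of all genes was 0.13, the list median was 0.17 (adjusted p = 0.796). The call was also lost with only the 2 groups compared (0.0857) and with the pancreas covariate (0.0627). Pancreatic genes had a median of 2.09 with 13 of 14 positive (adjusted p = 0.0464). That median turned to -0.48 without DSS replicate 1 (0.318), the DSS array with a low pancreas mean, and was 3.16 and 3.51 without DSS replicates 2 and 3, and the call was lost without replicates 1, 2 and 3 of DAPP before DSS (0.251, 0.129 and 0.175), control replicates 2 and 3 (0.0504 and 0.0516) and DAPP during DSS replicate 1 (0.0505). With equal medians (0.181), no background correction (0.0789), the authors' values (0.0789), no detection filter (0.0767) and array weights (0.16) it was lost too. Cytokine genes had a median of -0.01 (adjusted p = 0.989), neutrophil genes 0.31 (0.197), interferon genes -0.23 (0.276), junction genes -0.18 (0.237), NRF2 genes -0.08 (0.778) and goblet cell genes 0.03 (0.852), none of them past the threshold. The number of lists called was 8, and 4 without control replicates 2 and 3 each, 14, 3 and 2 without DSS replicates 1, 2 and 3, and 4 without each of DAPP before DSS replicates 2 and 3.

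When DAPP was given during DSS, inflammatory genes again lay close to their DSS levels, with S100a8 at -0.32 ± 0.37, S100a9 at -0.01 ± 0.42, Lcn2 at -0.17 ± 0.42, Il1b at -0.09 ± 0.38, Il6 at -0.49 ± 0.61 and Tnf at -0.26 ± 0.38. The 95% interval was -0.91 to 0.73 for Il1b and -1.08 to 0.74 for Lcn2. As lists, matrix genes lay higher than in DSS, and neutrophil, cytokine, ribosomal protein and pancreatic genes lay lower, by small amounts except for the pancreas. None of these 5 calls held, with adjusted p = 0.307 to 0.969 with an estimated correlation. The collagens Col3a1 and Col1a2 stood at 0.88 ± 0.23 and 0.83 ± 0.27.

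Limma called 0 of 11933 genes for DAPP during DSS against DSS (smallest adjusted p 1.0), and 318 had an unadjusted p under 0.05, 597 being the number with no effect. With array weights, eBayes trend, the replicate block and the authors' values the count was 0 as well. It was also 0 without replicate 1 of DAPP before DSS, which adds to the shared estimate of spread. Because of that spread, 318 against 597 does not show that there was no effect. Arrays did not overlap for 11.3% of genes, where chance gives 10%. Smallest in p among higher genes were Cma2, at least 1.72-fold, Cenpj at 1.09 ± 0.28, the cold-inducible RNA-binding gene Rbm3, at least 1.53-fold, the sterol desaturase gene Sc5d at 0.96 ± 0.25 and Dicer1, the small RNA processing enzyme, at 0.76 ± 0.19. Lower were Depp1 at -2.05 ± 0.61, Styxl1, at least 1.66-fold, Car14 at -0.76 ± 0.21 and Akt1, at least 1.39-fold. Cenpj and Sc5d were detected on 1 of 3 DSS arrays, and Car14 on 2 of 3 arrays of DAPP during DSS. Sc5d was the only member of the 36 lists past 0.05 adjusted over the list alone in this comparison. Barrier genes did not pass: Tjp1 stood at 0.55 ± 0.22, Muc2 at 0.61 ± 0.48, Ocln at 0.07 ± 0.31 and Cldn2 at -0.28 ± 0.57. The Muc2 difference was 0.18 without DSS replicate 1.

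Matrix and remodelling genes had a median of 0.38 with 18 of 23 positive (adjusted p = 0.000288, and adjusted p = 0.932 with an estimated correlation), and 0.37 without DSS replicate 3, where the call was lost (0.186). Its adjusted p ranged from 4.75e-08 to 0.186 over the alternatives other than an estimated correlation and fry. Its median was 0.68 with equal medians, which shifted the median of all genes to 0.35, and 0.23 without DAPP during DSS replicate 1. Neutrophil genes had a median of -0.28 with 4 of 19 positive (adjusted p = 0.0123, and adjusted p = 0.969 with an estimated correlation), the granule gene Ngp at -1.81 ± 0.71, the receptor gene Clec4e at -0.86 ± 0.36 and the growth factor receptor gene Csf3r at 0.73 ± 0.31. Without DSS replicate 1 the median turned to 0.05 (0.863), and the call was also lost without DSS replicate 2 (0.242) and without DAPP during DSS replicates 1 and 3 (0.0982 and 0.0742), with no detection filter (0.0815) and with array weights (0.0818). The median was -0.83 without DSS replicate 3, -0.50 and -0.17 without DAPP during DSS replicates 2 and 3, and -0.43 with the pancreas covariate. With equal medians it was 0.05, which is -0.30 relative to all genes. Ngp was detected on 2 of 3 arrays of each group, and Ifng on 1 of 3 of DAPP during DSS. Cytokine genes had a median of -0.20 with 8 of 26 positive (adjusted p = 0.0123, and adjusted p = 0.969 with an estimated correlation), Ifng at -0.87 ± 0.40 and Il1a at -0.77 ± 0.32. They stood at 0.09 (0.971) without DSS replicate 1, and lost the call without DSS replicate 2 (0.0722) and DAPP during DSS replicates 1 and 3 (0.0597 and 0.167), with no detection filter (0.0808) and with detection p under 0.01 on all 12 arrays (median -0.03, adjusted p 0.516). The cytokine median was -0.13 and -0.39 without DSS replicates 2 and 3, and -0.32 and -0.11 without DAPP during DSS replicates 2 and 3. With equal medians it was 0.16, which is -0.19 relative to all genes. Ribosomal protein genes had a median of -0.11 with 4 of 18 positive (adjusted p = 0.0123, and adjusted p = 0.307 with an estimated correlation). With equal medians it was 0.26, which is -0.10 relative to all genes, without a call (0.409), and the call was lost without DSS replicate 1 (0.0659) and DAPP during DSS replicate 1 (0.0892). Pancreatic genes had a median of -1.61 with 0 of 14 positive (adjusted p = 0.0172, and adjusted p = 0.969 with an estimated correlation). It turned to 0.37 without DAPP during DSS replicate 2 (0.836), and the call was lost without DSS replicates 2 and 3 (medians -0.58 and -0.14, adjusted p 0.468 and 0.894), DAPP before DSS replicate 1 (0.0661) and DAPP during DSS replicate 1 (0.242), with no detection filter (0.0815), with only the 2 groups compared (0.135) and with array weights (median -0.92, adjusted p 0.575). Without DSS replicate 1 and DAPP during DSS replicate 3 the pancreas median was -4.25 and -4.16. Lists not past the threshold included fibroblasts at 0.31 (0.0595), endothelium at 0.14 with 13 of 13 positive (0.0908), interferon at -0.22 (0.347), antimicrobial genes at 0.07 (0.733), NRF2 genes at -0.08 (0.602), oxidative phosphorylation at -0.06 (0.253) and colonocytes at -0.02 (0.733). The 5 list calls became 3 without DAPP during DSS replicate 1, and 8 without each of replicates 2 and 3 of that group. All 6 DAPP arrays were brighter before normalisation than the DSS arrays.

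**Figure D3:**
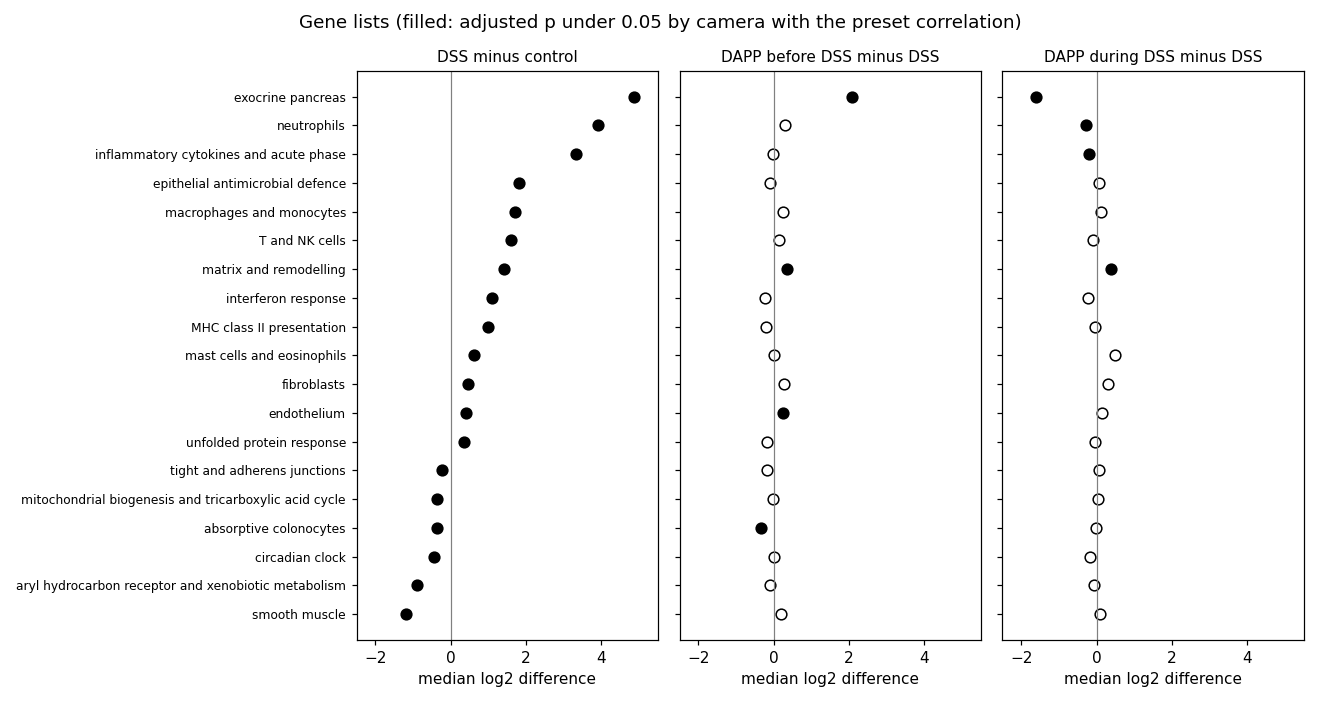
Median log2 difference (x axis) of the 19 gene lists called between DSS and control (y axis), for DSS minus control and for each DAPP group minus DSS, with filled points where the camera adjusted p at the preset correlation is under 0.05. Neutrophil genes lie at 3.91 for DSS minus control and at 0.31 and -0.28 for DAPP before and during DSS minus DSS.

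Against control, each DAPP group changed in the direction of the DSS group for nearly all of the 801 genes that differed between DSS and control. Of these, 800 had the sign of the DSS difference in DAPP before DSS and 801 in DAPP during DSS. The shared controls alone make signs alike: among the 801 genes of smallest p in each of 100 simulations with no effect, 679 to 729 and 678 to 727 had the same sign. In DAPP before DSS 439 of the higher and 268 of the lower genes were also called against control, where independent lists would share 29.2 and 16.6. In DAPP during DSS the numbers were 408 and 247 against 21.1 and 10.6. In neither group was a gene called in the opposite direction. Simulations with no effect gave at most 1 gene called in both. With no effect few genes can be called in either comparison, so that number is no baseline for the overlap of the real calls. The correlation of DSS minus control with DAPP before DSS minus control was 0.90 over genes, where 100 simulations with no effect gave 0.50 from the shared controls. The covariance was 0.605 against 0.061, a difference of 0.544. For DAPP during DSS the correlation was 0.93 against 0.50 and the covariance 0.517 against 0.061, a difference of 0.457. Genes are not independent replicates, and part of the excess in shared calls may come from the shared controls, since splitting 3 control arrays leaves a part with 1.

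**Figure D4:**
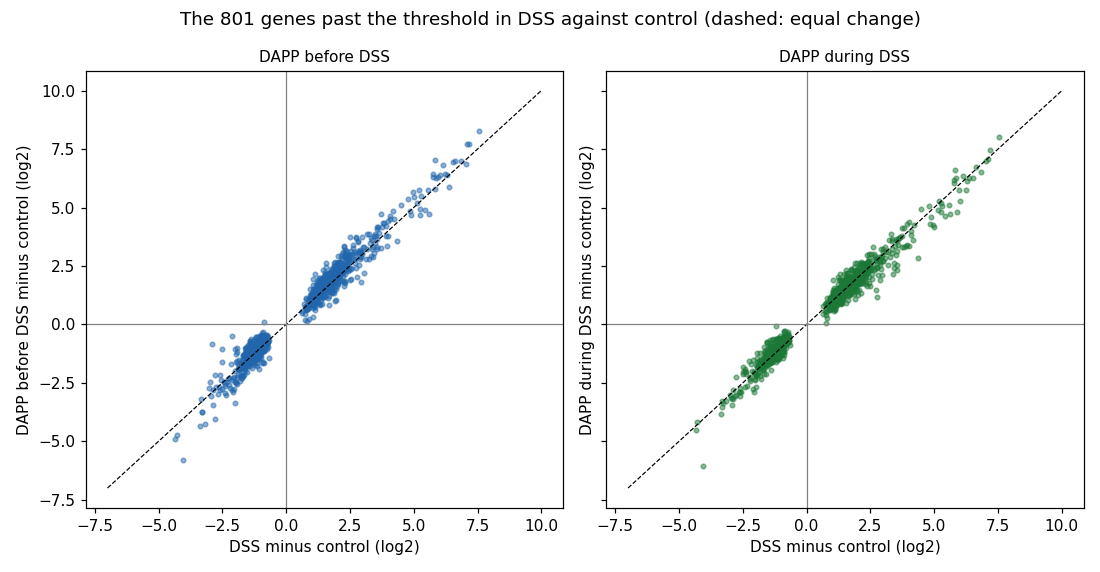
Log2 difference from control in each DAPP group (y axis) against that in DSS (x axis) for the 801 genes changed between DSS and control, 1 point per gene, with a dashed line of equality. The points run along the line in both panels, and 800 and 801 of them have the same sign on both axes.

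The position of these genes between DSS and control was measured with different DSS arrays on each side of the relation. On its scale -1 is the control level and 0 the DSS level. DAPP before DSS gave 0.12, 0.06 and 0.26 with DSS replicates 1, 2 and 3 held out (mean 0.15, SD 0.10). DAPP during DSS gave -0.03, 0.01 and 0.17 (mean 0.05, SD 0.10). The slopes rest on 429, 646 and 739 genes. With single arrays left out the mean for DAPP before DSS ranged from 0.02 (without DSS replicate 3) to 0.15 (without DAPP before DSS replicate 1), and for DAPP during DSS from -0.06 (without DSS replicate 3) to 0.09 (without DAPP during DSS replicate 2). Over the 801 genes, which were chosen on the same DSS arrays, the 95% interval of the single gene excluded a full return to control for 782 and 783 genes, and a return to the midpoint for 550 and 477. The correlation of DSS minus control with DAPP minus DSS, which share the DSS arrays with opposite sign, was 0.12 for DAPP before DSS and -0.24 for DAPP during DSS. Simulations with no effect in any group gave -0.50 for both. They lack the DSS effect, which by itself weakens this correlation, so the gap from -0.50 does not measure an effect of DAPP. The covariances were 0.035 against -0.061 and -0.053 against -0.062, differences of 0.0965 and 0.0088.

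No single gene passed the test between the DAPP groups, while pancreatic, neutrophil, immediate early, red blood cell and cytokine genes lay higher as lists in DAPP before DSS and cell cycle genes lay lower. None of these 6 calls held, with adjusted p = 0.756 to 0.944 with an estimated correlation. Depp1 stood at 2.61 ± 0.61 higher in DAPP before DSS, the steroid-induced gene Tsc22d3 at 1.02 ± 0.28, Map3k6 at 1.00 ± 0.26 and Car14 at 0.95 ± 0.21. Fbxo30 and Igip stood at -1.29 ± 0.31 and -1.19 ± 0.27, and Rbm3 was at least 1.47-fold lower. Limma called 0 genes (smallest adjusted p 0.84), with 485 at an unadjusted p under 0.05. The count was also 0 with array weights, eBayes trend, the replicate block and the authors' values, and 1 without DAPP before DSS replicate 1. The groups did not overlap for 7.90% of genes, where chance gives 10%.

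Neutrophil genes had a median of 0.57 for DAPP before minus DAPP during DSS with 16 of 19 positive (adjusted p = 0.000189, and adjusted p = 0.944 with an estimated correlation), the antimicrobial peptide gene Camp at 1.89 ± 0.72 and the chemokine Cxcl2 at 1.48 ± 0.53. Replicate 1 of DAPP before DSS deviated by 0.71 for this list. The list median was 0.30 with array weights and 0.88 with the pancreas covariate. Pancreatic genes had a median of 3.73 with 14 of 14 positive (adjusted p = 1.88e-05, and adjusted p = 0.944 with an estimated correlation), and 1.73 without DAPP during DSS replicate 2, where the call was lost (0.0999), and 6.23 without DAPP during DSS replicate 3. Immediate early genes had a median of 0.36 with 13 of 18 positive (adjusted p = 0.00798, and adjusted p = 0.756 with an estimated correlation), Dusp1 at 1.00 ± 0.39. They lost the call without DAPP before DSS replicate 2 (0.103), and their median was 0.23 without DAPP before DSS replicate 1. With equal medians it was 0.06, where the median of all genes was -0.22. Cell cycle genes had a median of -0.44 with 3 of 23 positive (adjusted p = 0.0141, and adjusted p = 0.944 with an estimated correlation), Top2a at -0.91 ± 0.47 and Mcm7 at -0.71 ± 0.49. Without DAPP before DSS replicate 2 that median was -0.09 (0.968), and the call was lost without DAPP during DSS replicates 2 and 3 (0.172 and 0.455) and with equal medians (-0.68, 0.0568). It was -0.88 without DAPP before DSS replicate 3, -0.81 and -0.18 without DAPP during DSS replicates 1 and 3, and -0.29 with no background correction and on the authors' values. Red blood cell genes had a median of 0.92 with 5 of 6 positive (adjusted p = 0.0429, and adjusted p = 0.944 with an estimated correlation), and replicate 1 of DAPP before DSS deviated by 1.32. That call was lost without control replicate 1 (0.0506), without DAPP before DSS replicates 1, 2 and 3 (0.129, 0.103 and 0.0993) and without DAPP during DSS replicates 2 and 3 (0.163 and 0.17), with no detection filter (0.0896) and with only the 2 groups compared (0.0582). The median was 0.53, 1.13 and 1.09 without DAPP before DSS replicates 1, 2 and 3, and 1.52 and 0.59 without DAPP during DSS replicates 1 and 2. Cytokine genes had a median of 0.25 with 20 of 26 positive (adjusted p = 0.0472, and adjusted p = 0.944 with an estimated correlation). Their call was lost without control replicate 1 (0.0506), DSS replicate 1 (0.0567), DAPP before DSS replicates 2 and 3 (0.227 and 0.228) and DAPP during DSS replicates 1 and 3 (0.133 and 0.214), with no detection filter (0.149) and with detection p under 0.01 on all 12 arrays (0.0733). The cytokine median was 0.40 and 0.15 without DAPP during DSS replicates 2 and 3, 0.16 with array weights and 0.48 with the pancreas covariate. With equal medians it was 0.12, again beside a median of all genes of -0.22. The 6 list calls became 10 without DAPP during DSS replicate 1 and 3 without its replicate 2.

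Relative to control, inflammatory and matrix genes were higher in DAPP before DSS, in list calls that were lost with an estimated correlation. Neutrophil genes rose in 18 of 19 cases with a median of 4.22, cytokine genes in 19 of 26 with a median of 3.11, macrophage genes in 13 of 16 with a median of 1.84 and matrix genes in 17 of 23 with a median of 1.82, each with adjusted p = 0.0584 with an estimated correlation. With no background correction the neutrophil and cytokine medians were 2.28 and 1.78, on the authors' values 2.26 and 1.77, and with detection p under 0.01 on all 12 arrays 1.95 for cytokines. Among the rises were Reg2, at least 297-fold (limma adjusted p = 0.02), Reg3b by 8.29 ± 0.52 to a level near the highest of any probe (14.96 of 15.09), Reg3a, at least 131-fold, and Reg1 by 8.17 ± 2.24. Reg1 was detected on 1 of 3 control arrays and Reg3b on 2 of 3, so their differences are not bounds and have no order against those of Reg2 and Reg3a. Reg1, Reg2 and Reg3a follow the pancreas list from array to array. Reg2 lost its call without control replicates 1, 2 and 3 (0.0595, 0.062 and 0.065), Reg1 without control replicates 1, 2 and 3 (0.0821, 0.104 and 0.104), DAPP before DSS replicates 1, 2 and 3 (0.0791, 0.0508 and 0.067) and DAPP during DSS replicate 1 (0.0521), and Reg3a without control replicates 1, 2 and 3 (0.0968, 0.0952 and 0.104), DAPP before DSS replicates 1 and 3 (0.0809 and 0.07) and DAPP during DSS replicate 1 (0.0519). Among the falls were Mptx1 at -5.80 ± 0.85, Slc37a2 at -4.74 ± 0.56, Tgm3 at -4.24 ± 0.59, the muscle enolase Eno3 at -4.03 ± 0.60 and Ppargc1a at -3.15 ± 0.66 (limma adjusted p = 0.0098), Tgm3 and Ppargc1a being detected on 2 of 3 arrays of DAPP before DSS. Smooth muscle genes fell in 7 of 13 cases (adjusted p = 0.268 with an estimated correlation), and xenobiotic metabolism genes in 5 of 17 with a median of -1.01 (adjusted p = 0.268 with an estimated correlation), and -0.59 with no detection filter. Colonocyte genes had a median of -0.82 and junction genes of -0.52 (adjusted p = 0.407 and adjusted p = 0.406 with an estimated correlation), and -0.23 and -0.13 without replicate 1 of DAPP before DSS, where both calls were lost (0.102 and 0.168). With array weights the medians were -0.32 and -0.14, and the junction call was lost (0.0706). The junction median was -0.29 with no background correction and on the authors' values, -0.34 with an offset of 50, -0.22 with equal medians, -0.33 without control replicate 3 and -0.79 without DAPP before DSS replicate 2.

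In all, limma called 1338 genes between DAPP before DSS and control, 748 higher and 590 lower, and 20 lists. Pancreatic genes had medians of 5.25 to 7.56 over the alternatives other than an estimated correlation and fry, and did not pass with an estimated correlation. The gene count was 815, 776 and 785 without control replicates 1, 2 and 3, and 1543 without replicate 1 of DAPP before DSS. With the pancreas list mean as a covariate it was 684, of which 653 were among the 1338. The covariate follows the groups here, so the lost calls do not tell their source. With equal medians it was 1345, of which 79.6% were higher against 55.9% with quantiles, and the median of all genes shifted to 0.13. Between DAPP during DSS and control 917 genes were called, 541 higher and 376 lower, and 19 lists. That count was 537, 540 and 520 without control replicates 1, 2 and 3, 610, 443 and 521 without DAPP during DSS replicates 1, 2 and 3, and 1722 without replicate 1 of DAPP before DSS. With equal medians it was 1708, of which 90.0% were higher against 59.0%, and the median of all genes shifted to 0.38. Without overlap between arrays were 29.2% and 40.8% of genes, where chance gives 10%.

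In DAPP during DSS neutrophil genes were higher than in control in 16 of 19 cases with a median of 3.34 and macrophage genes in 12 of 16 with a median of 1.75 (both adjusted p = 0.0509 with an estimated correlation). Cytokine genes rose in 18 of 26 cases with a median of 2.82 and matrix genes in 17 of 23 with a median of 1.93, and these calls held with an estimated correlation (adjusted p = 0.034 for both). With no background correction the neutrophil and cytokine medians were 1.61 and 1.52, and with detection p under 0.01 on all 12 arrays 1.80 for cytokines. Reg3b rose by 8.02 ± 0.52 to 14.69 ± 0.27, Saa3 by 7.45 ± 0.41, S100a9 by 7.09 ± 0.42 and Mmp10 by 6.75 ± 0.32, and Reg3g was at least 55.9-fold higher. Lower were Mptx1 at -6.07 ± 0.85 (limma adjusted p = 0.0011), Mettl7a2 at -4.52 ± 0.28, Slc37a2 at -4.18 ± 0.56, Odf3b at -3.54 ± 0.33 and Bex4 at -3.43 ± 0.35. Mettl7a2 and Odf3b were detected on 2 of 3 arrays of DAPP during DSS. Smooth muscle genes fell in 6 of 13 cases with a median of -1.06 (adjusted p = 0.195 with an estimated correlation, and a median of -0.57 with equal medians, which raised the median of all genes too), and xenobiotic metabolism genes in 4 of 17 with a median of -0.78 (adjusted p = 0.204 with an estimated correlation). The latter median was -0.38 with no background correction, -0.42 with equal medians under the same rise of all genes, -0.49 with no detection filter and -1.19 with detection p under 0.01 on all 12 arrays. Antimicrobial genes rose in 9 of 20 cases and fell in 2, with a median of 1.81 (adjusted p = 0.0898 with an estimated correlation), 1.17 with no background correction and 1.09 without control replicate 3. Hmox1 rose by 2.70 ± 0.39, and Ppargc1a stood at -2.21 ± 0.66 (limma adjusted p = 0.067). Pancreatic genes had a median of 3.39 (adjusted p = 0.55 with an estimated correlation), 5.28 without DAPP during DSS replicate 2, and 0.80 without DAPP during DSS replicate 3, where the call was lost (0.609). With equal medians that call was lost as well (0.542).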

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

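The tests of whether DSS itself raises pancreatic genes, of brightness as the source of the pancreatic genes and of lymphoid tissue were chosen only after the result was seen, as was the pancreas list mean as a covariate.

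Between the DAPP groups 6 gene lists differed by a test of the difference itself at camera's preset correlation, with DAPP before minus DAPP during DSS medians of 0.57 for neutrophils, 0.25 for cytokines and acute phase genes, -0.44 for cell cycle genes, 0.36 for immediate early genes, 0.92 for red blood cells and 3.73 for the exocrine pancreas. None of the 6 passed with an estimated correlation or with fry (0 lists each). Probes with no gene listed, which enter no comparison above, also changed: of 3507 detected, 59 were higher in DSS than in control, 112 in DAPP before DSS and 86 in DAPP during DSS, and 50, 95 and 63 were lower.

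Pancreatic enzyme genes were high on some arrays of the DSS and DAPP groups and low on others of the same groups. A rise that DSS causes in the colon itself stays open: DSS replicate 1 lay below the highest control array (difference -1.41 on the log2 scale), but this is 1 array of the DSS group, and it lay above the other control arrays. DAPP during DSS replicate 2, given DAPP as well as DSS, had a list mean of 5.81, below all control arrays (5.98 to 7.70). Array brightness is argued against by a range of 8.02 in the list mean within the DAPP during DSS arrays. Pancreatic tissue in the colon sample remains a candidate explanation: of a second list of pancreatic genes, 85.7% were higher on the array with the higher enzyme mean in both pairs of arrays compared, although 9 of its 14 tested members were also detected on all control arrays. The pairs hold the highest and lowest enzyme means of their groups. A rise in the colon itself could carry these genes too, so the second list does not separate these explanations. The islet gene Ppy was higher in the DSS pair (8.55 against 7.77) but lower in the DAPP during DSS pair (7.43 against 7.89). Amy2a5, an abundant pancreatic gene, was at 15.03 on DSS replicates 2 and 3 and at 10.98 on DSS replicate 1.

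Replicate 1 of DAPP before DSS stood apart from the other 11 arrays. Its deviation correlated with the DSS-minus-control change at 0.121 over all tested genes, under the bound set beforehand against a stronger form of the DSS response. Genes that DSS leaves unchanged and the noise of 1 array lower this value, so it cannot exclude a stronger response in part of the genes. Lists went both ways. Smooth muscle (-0.63) and colonocyte genes (-1.28) deviated in the direction of DSS, and interferon (-0.72), matrix (-0.64) and antimicrobial genes (-0.59) against it. Loss of signal probe by probe was not decided, since different probes of a gene deviated together with a correlation of 0.457 over 4638 pairs, between the bounds set for either answer. This array had the fewest detected probes of all, 17650, against 20027 to 21444 on the other DAPP arrays. Its mean raw signal, 601, was the lowest of the DAPP arrays. Lymphoid tissue in the sample is a candidate explanation, with a median deviation of 1.34 over 17 T, NK, B and plasma cell genes, of which 6 were detected on all control arrays, at percentile 100 of matched random lists. The deviation was not specific to these genes, with red blood cell genes at 1.32, pancreatic genes at 1.31 and neutrophil, endothelial and macrophage genes at 0.71, 0.71 and 0.69, and the lower colonocyte genes stay open, and a difference of this mouse in its biology was not tested.

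Matrix and remodelling genes lay higher as a list in both DAPP groups than in DSS at camera's preset correlation, a call lost with an estimated correlation (adjusted p 0.86 and 0.932) and with fry (0.856 and 0.996). The list's median lay at percentile 100 of random lists matched on mean level in both comparisons. A brightness effect set by the mean level alone would shift those lists as well, and only this form is argued against. The list was picked for its shift, and the random lists ignore the correlation between its members. The percentile therefore cannot decide on chance or on a brightness effect of another form. The outcome set beforehand for a single DSS array was met, since both calls were lost without DSS replicate 3. The list stayed past the threshold in 3 of 6 settings without 1 DSS array. Without DSS replicate 3 the median went from 0.36 to 0.20 for DAPP before DSS but stayed at 0.37 (0.38 with all arrays) for DAPP during DSS. The mean over members went from 0.26 ± 0.42 to 0.14 ± 0.44 (SD over genes) and from 0.31 ± 0.41 to 0.18 ± 0.60. A single DSS array thus remains a candidate explanation, although a call can also be lost because fewer arrays are used. A slide or scan difference cannot be told apart from the DAPP groups, since 0 DAPP arrays lie within the brightness range of the control and DSS arrays. An effect of DAPP was not tested apart from these.

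Other splits of the 6 arrays of each comparison into 3 against 3 are too few, at 10, for a share under 0.05. As many genes as in the real split were called in 1 of 10 splits for DSS against control (801, highest other 0), 1 for DAPP before DSS against control (1338, highest other 1) and 1 for DAPP during DSS against control (917, highest other 0). For the comparisons with 0 genes all 10 splits gave as many, an outcome that a real count of 0 fixes, with a highest other of 64 for DAPP before DSS against DSS, 32 for DAPP during DSS against DSS and 0 between the DAPP groups. Splits that call 64 and 32 genes where the real ones call 0 point to a structure of the samples. The split with 32 genes set the arrays with low pancreas list means (6.29, 8.53 and 5.81) against those with high means (12.8, 13.5 and 13.8). Of its 32 genes 12 are on the pancreas list, and Clps, Ctrl, Gp2 and Sycn are on the second list of pancreatic genes. Others among them, such as Try10, Prss3, Pnliprp2, Reg1 and Reg2, are on neither list. These counts therefore do not mean that the rest are unrelated to the pancreas. Of the 64 genes 0 are on the pancreas list. The source of these structures was not tested.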

How the results depend on the processing

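The pancreas list mean as a covariate and the slopes with arrays left out were chosen after seeing the data. Of the 137 tested genes that the rule for named genes selected for DSS against control, 76 were called, 52 of them in every alternative run. For DAPP before DSS against control 82 of 130 were called, 46 of them in every alternative. For DAPP during DSS against control 68 of 127 were called, 41 of them in every alternative. The rule favours large or clear differences, so these shares do not describe all called genes. Of the lists called, 4 of 19, 0 of 20 and 2 of 19 kept their call throughout, and 0 of 8, 0 of 5 and 0 of 6 in the comparisons without control. Scaling to equal medians gave 1708 genes for DAPP during DSS against control. It moves all genes together, with a median of all genes of 0.13 for DAPP before DSS against DSS and against control, 0.35 for DAPP during DSS against DSS and 0.38 for DAPP during DSS against control, so a changed sign alone is no change of direction. Oxidative phosphorylation stood at 0.17 for DAPP before DSS against DSS, 0.21 for DAPP before DSS against control and 0.32 for DAPP during DSS against control, which is 0.04, 0.07 and -0.05 relative to all genes, with no call. Ribosomal proteins stood at 0.38 and 0.50 for DAPP before DSS against DSS and control, 0.25 and 0.37 relative to all genes. Both were called by camera under this scaling (adjusted p 0.000295 and 0.00525), where quantiles gave no call. For DAPP during DSS against DSS they stood at 0.26, which is -0.10 relative to all genes, with no call. Detection p under 0.01 on all 12 arrays, which leaves 7593 genes and 27 lists, gave 487, 821 and 587 genes for DSS, DAPP before and DAPP during DSS against control, 12 and 11 lists for DSS and DAPP during DSS against control, and 2 lists for DAPP during DSS against DSS, as did no detection filter (2). Only the 2 groups compared gave 746 genes for DAPP before DSS against control, 67.6% of them higher, and 2352 for DAPP during DSS against control. Array weights gave 1479 genes for DSS against control, 3392 for DAPP during DSS against control and 4 lists for DAPP before DSS against DSS. An estimated correlation in camera left 4 lists for DSS against control, 2 for DAPP during DSS against control and 0 in each of the other comparisons. Fry gave 15, 21 and 19 lists for DSS, DAPP before and DAPP during DSS against control. In each comparison without control fry gave 0 lists. The pancreas covariate gave 606, 684 and 795 genes for DSS, DAPP before and DAPP during DSS against control, and 11 lists between the DAPP groups.

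With each array left out in turn, genes changed numbered 429 to 1523 for DSS against control, 776 to 1543 for DAPP before DSS against control, 443 to 1722 for DAPP during DSS against control and 0 to 1 between the DAPP groups. Lists numbered 2 to 14 for DAPP before DSS against DSS, 3 to 8 for DAPP during DSS against DSS and 3 to 10 between the DAPP groups. The position between DSS and control ranged from 0.0155 to 0.15 for DAPP before DSS and from -0.0620 to 0.0876 for DAPP during DSS. List medians that turned, or whose test turned, included colonocytes (-0.69 to 0.12), goblet cells (-0.27 to 0.27) and pancreas (-0.48 to 3.51) for DAPP before DSS against DSS. For DAPP during DSS against DSS they included neutrophils (-0.83 to 0.05), cytokines (-0.39 to 0.09), cell cycle (-0.39 to 0.36) and pancreas (-4.25 to 0.37). Between the DAPP groups they included cell cycle (-0.88 to -0.0871). Except where fewer genes or arrays were used, the cause was not tested. Replicate numbers mostly did not pair the arrays: same-numbered arrays correlated at -0.32 to 0.40 in their deviations, and the own number was the best match in 4 of 18. The 3 of 18 pairs over 0.1 were all between the arrays numbered 3 of the DSS and DAPP groups (0.40, 0.35 and 0.11). With the replicate block 812 genes changed for DSS against control. A slide block was not run, since no slides are named in the files used. Signal over background limits genes near the floor of 5.18 to 5.70. Folds are bounds only for genes detected on no array of the dimmer group, and those detected on some of its arrays have plain differences.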

Other observations

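The splits and genes described here were picked only after their values were seen, and no explanation of them was tested. Setting DSS replicates 1 and 3 and DAPP before DSS replicate 3 against the other 3 arrays of these groups called 64 genes, 41 higher and 23 lower. The largest log2 differences among the 64 were Neurog3 (2.59), Mcm3 (2.21) and Tgm3 (1.99) for the higher and Ceacam12 (-2.92), 1810009J06Rik (-2.90) and Angptl7 (-2.51) for the lower genes, and no gene list was tested on them. Setting DSS replicate 1 and DAPP during DSS replicates 1 and 2 against the other 3 arrays of these groups called 32 genes, all lower. Of these, 12 are on the pancreas list, and Clps, Ctrl, Gp2 and Sycn are on the second list of pancreatic genes. The rest are on neither list, which does not make them unrelated to the pancreas. The largest differences were those of Try10 (-8.08), Cela3b (-7.88) and Try4 (-7.84), and Reg1 (-7.41), Reg2 (-7.27) and Reg3a (-7.12) were also among them.

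Replicate 1 of DAPP before DSS had 382 genes lower and 267 higher by over 2 on the log2 scale than the other arrays of its group. The largest deviations were those of Glycam1 (5.54), Mat1a (4.66), Erp27 (3.93), Serpini2 (3.89) and Mzb1 (3.88) for the higher genes and of St6galnac6 (-6.29), Pfn1 (-5.57) and Ceacam1 (-5.08) for the lower. The antimicrobial gene Ang4 was at 14.09, 13.49 and 9.16 on the control arrays.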
